A study of Mus musculus with 6 samples.

How the data were processed

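Total RNA was profiled in 6 libraries of mouse bone-marrow-derived dendritic cells, 3 given PBS and 3 given Latilactobacillus sakei Wikim0185 for 6 h. Per the labels' protocols, female BALB/c mice aged 8 weeks gave the marrow, GM-CSF was added at 20 ng/ml, cells were collected on day 8, and 5 bacteria were added per cell. The libraries were made with the SMARTer Universal Low Input kit, per the labels' protocols, and whether strand was kept is not given in the sources used here. All 6 libraries carry one batch label, so no comparison between batches was possible. The labels number the replicates in both groups but do not say whether they were separate cultures or animals. The p-values then measure only the spread between these samples, which may be technical.

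The deposited count table holds raw read counts per gene for 45777 genes, per the file headers, and the counts were used as the authors deposited them. The deposited FPKM tables, 1 per group, hold FPKM, fragments relative to gene length and library size, as computed by the authors, per the file headers. Per the submitters' processing notes, Trimmomatic 0.38, HISAT2 2.1.0, SAMtools 1.9, StringTie 2.1.3b and the mm10 genome were used; their order is not given. How reads were assigned to overlapping or near-identical genes, the strand setting, and whether both mates of a pair were counted are not given in the sources used here. A value of 2 occurred more often than a value of 1 in the count table (4964 against 3912), so counting error computed from these values can be too small. The columns headed Control were taken as the PBS libraries, the only control samples among the labels, by their replicate numbers. Identifiers are NCBI Gene numbers, of which 45679 were found in the RefSeq annotation of GRCm38.p6, and 26 symbols turned into dates were restored through these numbers. Coordinates are from that annotation, on the same assembly as mm10, 1-based. Over 8701 genes with more than 200 counts in each library, the counts per FPKM unit followed the library totals to within 0.06 (log2) in every library, so both FPKM tables stand on 1 scale, that of the library totals.

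Library totals ran from 51563836 to 63247456 counts. Genes were kept with filterByExpr at its defaults (a minimum count of 10 scaled to depth), which left 15955 genes (34.9% of the table). Library sizes were scaled with TMM factors, which were 1.25 to 1.29 in PBS and 0.77 to 0.82 in Wikim0185 libraries. Expression is given as CPM, counts relative to the scaled library size, as mean ± SD over 3 libraries. The groups were compared with the quasi-likelihood test of edgeR 4.0.16 (robust, group as the only term, R 4.3.3), two-sided, and p-values were adjusted by Benjamini-Hochberg over all tested genes. A gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was its absolute value divided by the square root of the F statistic. Where a group had 0 counts in its 3 libraries, the fold is given as a lower bound against 3 counts over the group, and such bounds cover counting error only.

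Before the data were examined, 35 gene lists were fixed (22 pathways, 11 sets of cell type markers, 2 sets on RNA quality), together with the tests, the alternatives and the rule for genes named in the text. The rule takes the 10 largest rises and the 10 largest falls among called genes with a proper symbol, at least 5 CPM in the higher group and no overlap between the groups, up to 3 called members of each list with the largest change and at least 1 CPM, and a panel of 12 genes whatever their result. Other genes named below were chosen after their values were seen. Some members of the lists and families are not reported here by name. Lists with at least 3 measured members, 32 of the 35, were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists; camera with an estimated correlation and fry were run beside it. Camera asks whether a list moved more than other genes, and fry whether its members moved on balance in 1 direction.

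The alternatives were DESeq2 size factors or plain library totals in place of TMM, no filter and a stricter filter, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-voom, limma-trend on the deposited FPKM as log2(FPKM + 1) for genes with a mean of at least 1, and other thresholds. Protein-coding genes alone, and removal of trends with transcript length and GC content (transcripts of GENCODE M21), were added after the data had been seen. No pair of libraries within a group held identical values, and each pair differed by more than counting noise (chi-square per degree of freedom 13.1 to 121.4). None was treated as a repeat deposit, and these values do not show whether the libraries came from separate cultures. The tests were tried on simulated counts for this comparison, drawn 5 times, with an average of 15344 genes tested and, over the draws, 239, 240, 237 and 239 tested genes changed 1.5-, 2-, 4- and 8-fold: edgeR recovered 23% of genes changed 1.5-fold, 64.6% at 2-fold, 93.2% at 4-fold and 96.2% at 8-fold, and 9% of its calls were false, above the 5% aimed at. The number of draws was raised to 5 after 1 draw had been seen. DESeq2, on 1 draw, made 20.6% false calls, and limma-voom 7.2% on 5. In each draw far fewer genes were changed than were called in the data, so these shares of recovered and false calls need not hold for this comparison. With no gene changed edgeR made 0 calls on 15955 simulated genes, which were filtered again before the test. The list test called the 1 shifted list and 0 of the unchanged lists in a simulation with 32 lists. Genes were drawn independently there, while the estimated correlation in the data reached 0.684 for oxidative phosphorylation genes. The simulation could thus not show false list calls that arise from correlated genes. Gene families outside the lists were defined by symbol after the values were seen, 14 in all. Figures were drawn with matplotlib 3.10.9.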

Results

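The series profiled the transcriptome of bone-marrow-derived dendritic cells, antigen-presenting cells grown from mouse marrow with the growth factor GM-CSF, after 6 h with Latilactobacillus sakei Wikim0185, a lactic acid bacterium, or with PBS as the vehicle. The series title places the work in allergic asthma and names tolerogenic dendritic cells, those that restrain T cell responses, and epigenetic change. Each group held 3 libraries. The total counts were 51563836, 58670445 and 54556662 in PBS replicates 1 to 3 and 53058783, 63247456 and 53376047 in Wikim0185 replicates 1 to 3.

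Exposure to Wikim0185 was followed by large rises of cytokine, prostaglandin and nitric oxide genes. Il23a, which encodes a subunit of interleukin-23, had 0 counts in the 3 PBS libraries and 3267 in the 3 Wikim0185 libraries, at least 1700-fold higher. U90926 likewise had 0 counts in PBS and was at least 370-fold higher. Il6 rose from 1.596 ± 0.4302 to 2461 ± 608 CPM (n = 3 per group, as for all values below), a log2 fold change of 10.58 ± 0.32 (SE). The inducible cyclooxygenase gene Ptgs2 rose from 4.64 ± 0.652 to 6508 ± 361 CPM and the inducible nitric oxide synthase gene Nos2 from 0.192 ± 0.0605 to 288 ± 65.7 CPM. The remaining genes among the 10 largest rises were Ifnb1 (log2 fold change 10.60), Il12a (10.29), Clic5 (10.23), Il10 (9.58) and Il27 (9.25), and the log2 fold changes of Ifnb1, Il12a and Clic5 rest on 7, 6 and 4 counts in PBS.

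The 10 largest falls were led by Neurl1b (−5.25) and Cx3cr1, the fractalkine receptor, which fell from 9.62 ± 1.401 to 0.279 ± 0.138 CPM. Cd101 (−5.04) and Skint3 (−4.77) followed. Cd300lb, of the Cd300 family of myeloid receptors, fell from 62.6 ± 5.11 to 2.43 ± 0.132 CPM (−4.69 ± 0.12). Ppargc1b, a transcriptional coactivator of mitochondrial genes, fell from 14.3 ± 1.402 to 0.833 ± 0.396 CPM, and Dnajc28 (−4.46), Npas4 (−3.95), Tmem150b (−3.93) and Galnt9 (−3.93) completed the group. The adjusted p of these 10 falls was at most 1.11e-05 by edgeR.

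In all, edgeR called 9370 of 15955 tested genes (58.7%), 4458 higher and 4912 lower in Wikim0185, and 4876 of them had changed at least 2-fold (2386 higher, 2490 lower). Over 4-fold, 1110 genes were higher and 784 lower. The values of the groups did not overlap in 66.9% of the tested genes, where chance gives 10%. The split between higher and lower depends on the scaling. When libraries were scaled to their totals the median of all genes shifted by −0.69 (log2), and 2077 genes were called higher and 9684 lower; fold changes below are relative to TMM, and a log2 change of between 0 and about 0.69 has the opposite sign on library totals. Genes that rose over 4-fold held 3.59 ± 0.14% of the counts in PBS and 22.57 ± 0.93% in Wikim0185 libraries.

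**Figure D1:**
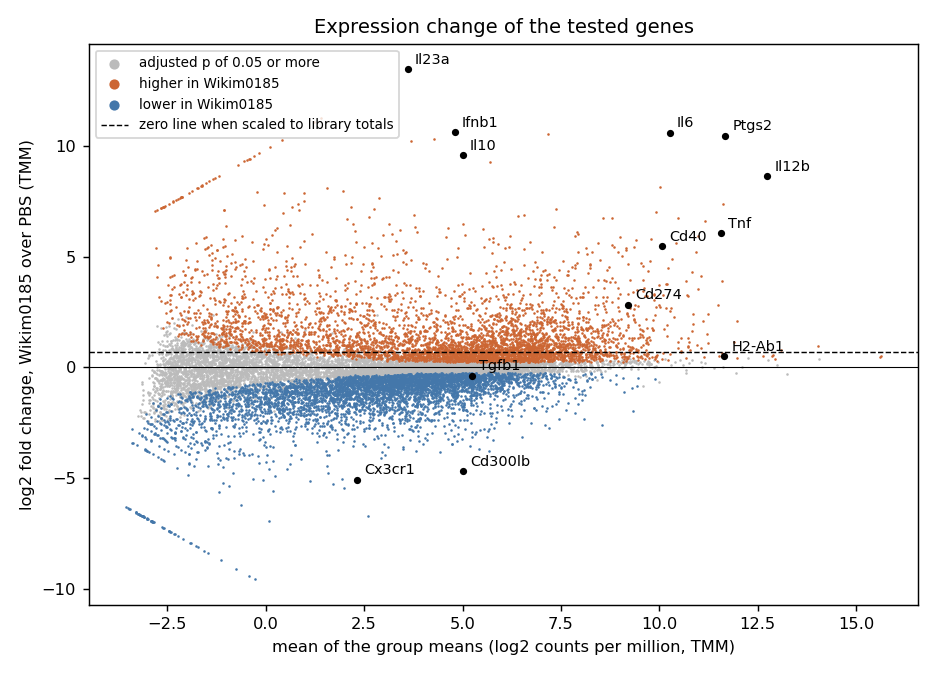
Log2 fold change of Wikim0185 over PBS (y axis, TMM scaling) against the log2 of the mean of both group means in CPM (x axis), 1 point per tested gene, with called genes in colour. The 4458 called rises reach a fitted 13.45 for Il23a, the dashed line marks where no change lies under scaling to library totals, and the slanted streaks of points at low abundance are genes with 0 counts in 1 group, whose plotted change depends on the prior count.

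The libraries separated by treatment. The first principal component of the 500 most variable genes held 91.6% of the variance and parted the PBS from the Wikim0185 libraries. Spearman correlations across genes, which are not independent replicates, were 0.9927 to 0.9955 within PBS, 0.9856 to 0.9925 within Wikim0185 and 0.9212 to 0.925 between the groups. Wikim0185 replicate 1 gave the lowest correlations within its group. More genes had at least 1 count in PBS (20262 to 20844) than in Wikim0185 libraries (19187 to 19689).

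All 19 measured members of the proinflammatory cytokine list rose, with a median log2 fold change of 5.78, which is the same with the members at 0 counts in PBS set to their bound. Il12b, which encodes the subunit shared by interleukin-12 and interleukin-23 (gene 16160, mm10 chromosome 11, 44400063 to 44414677), rose from 34.4 ± 5.66 to 13587 ± 3246 CPM (8.63 ± 0.28; adjusted p = 8.09e-08 by edgeR). Tnf rose from 90.5 ± 2.29 to 5989 ± 1008 CPM (6.05 ± 0.17; adjusted p = 4.67e-08 by edgeR). Il6 lies on chromosome 5, 30013114 to 30019975 and Il23a on chromosome 10, 128296140 to 128298084. Of the chemokine list, 17 of 19 members rose and 0 fell (median 4.05). On library totals 18 cytokine and 16 chemokine genes rose and 0 fell. The neutrophil attractants Cxcl1 and Cxcl2 rose from 7.35 ± 1.18 to 2050 ± 549 CPM and from 65.1 ± 14.04 to 3975 ± 736 CPM, and the interferon-induced Cxcl10 from 16.9 ± 3.02 to 1014 ± 84.9 CPM. Both lists were called by camera (adjusted p = 3.18e-12 and 1.3e-09); the adjusted p was 0.138 for each with an estimated correlation.

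Interferon-stimulated genes rose as a group, with 32 of 32 members higher and a median of 4.68. Rsad2, the antiviral protein viperin, rose from 37.4 ± 0.588 to 6219 ± 888 CPM (7.38), its neighbour Cmpk2 from 14.9 ± 0.602 to 1927 ± 314 CPM (7.01) and the immunity-related GTPase gene Iigp1 from 1.47 ± 0.187 to 169 ± 11.97 CPM (6.85). The list's camera adjusted p was 1.66e-21, and the adjusted p was 0.138 with an estimated correlation.

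Of the NF-kB targets and feedback inhibitors, 21 of 22 rose and 0 fell (median 1.63). On library totals 16 rose and 0 fell. They included the NF-kB regulator Nfkbiz (5.02), the phosphatase gene Dusp2 (3.39) and Tnfaip3 (2.82), which encodes the inhibitor A20. Of the antimicrobial effectors and inflammatory enzymes, 15 of 19 rose and 0 fell (median 2.57), against 13 and 4 on library totals. They included Nos2, Ptgs2 and the ectoenzyme gene Cd38 (4.76). Camera called these lists at adjusted p = 1.92e-09 and 1.98e-06, and with an estimated correlation the adjusted p was 0.138 and 0.372. Genes of microbial pattern recognition moved both ways, with 15 of 30 higher and 6 lower (7 lower when adjusted over the list alone) and a median of 0.52 (−0.15 on library totals, with 14 higher and 14 lower). The double-stranded RNA sensor Tlr3 (4.37), the kinase Ripk2 downstream of NOD receptors (3.95) and the scavenger receptor Marco (3.77) rose. That list was called at an adjusted p of 0.0147, and the adjusted p was 0.482 with an estimated correlation.

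All 17 measured members of the co-stimulation and maturation list rose (median 2.36), and on library totals 14 rose and 1 fell. Cd40 rose from 48.00 ± 14.01 to 2113 ± 223 CPM (5.46 ± 0.23), Cd80 from 25.1 ± 6.73 to 135 ± 15.4 CPM (2.42 ± 0.19) and Cd86 from 91.4 ± 6.91 to 439 ± 79.99 CPM (2.26 ± 0.15), the last 2 being ligands of CD28 on T cells; Tnfsf15 (5.21) and Cd70 (4.01) also rose. Camera gave an adjusted p of 4.25e-08, and the adjusted p was 0.35 with an estimated correlation. Genes of MHC class I presentation rose in 14 of 16 cases and fell in 0 (median 1.78; 14 higher and 2 lower on library totals; camera adjusted p = 1.63e-07; adjusted p = 0.138 with an estimated correlation), including the transactivator Nlrc5 (3.17), the peptide transporter gene Tap1 (2.75) and the immunoproteasome gene Psmb10 (2.27).

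MHC class II presentation was called by fry (adjusted p = 0.0336) and not by camera (median 0.29; adjusted p = 0.104), with 8 of 16 members higher and 2 lower, against 1 higher and 9 lower on library totals. H2-Ab1, 1 chain of the class II molecule, rose from 2638 ± 351 to 3770 ± 471 CPM (0.52 ± 0.14; adjusted p = 0.013 by edgeR), and its change was −0.17 on library totals. Its adjusted p was 0.0598 without PBS replicate 1 and 0.0612 without PBS replicate 2, and that of H2-Eb1 (0.53; −0.15 on library totals) was 0.0516 without PBS replicate 2. Ctsl (1.38) and H2-Eb2 (1.03; 0.34 with an adjusted p of 0.119 on library totals) also rose. The 2 lower members, named after their values were seen, were H2-DMa (−0.37) and Marchf1 (−0.28), and Marchf1 was no longer called without PBS replicate 1 or 2 or without any 1 of the Wikim0185 replicates (adjusted p 0.0707 to 0.162 in these fits), with size factors (0.09) or by DESeq2 (0.0578), while H2-DMa had an adjusted p of 0.141 with length and GC trends removed. The list was called by camera without Wikim0185 replicate 1 (median 0.39, adjusted p = 0.035).

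**Figure D2:**
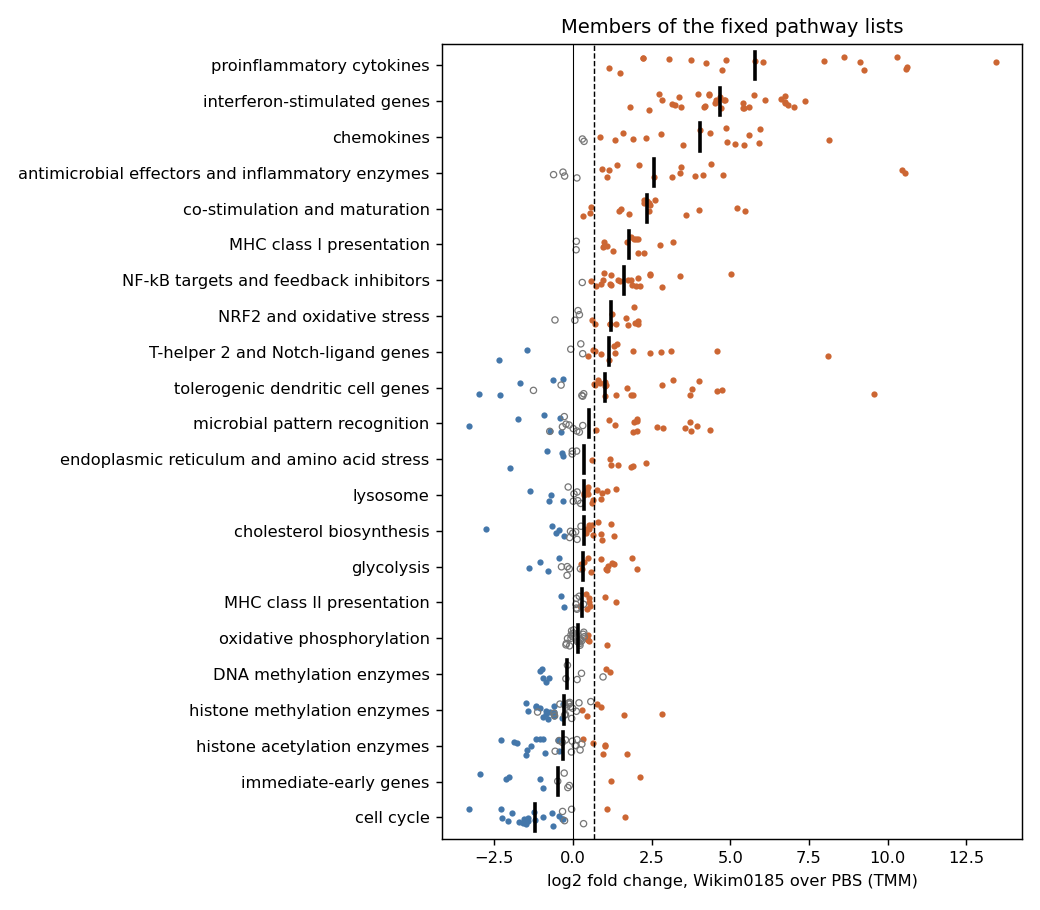
Log2 fold change of Wikim0185 over PBS (x axis, TMM scaling) for each measured member of the 22 fixed pathway lists (y axis), with orange points for called rises, blue points for called falls, open circles for genes that were not called, and a bar at the list's median. Medians run from −1.22 for cell cycle genes to 5.78 for proinflammatory cytokines, and the dashed line marks no change under scaling to library totals, to the left of which a change is a fall on that scale.

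Of 30 measured genes of the tolerogenic dendritic cell list, 20 rose and 5 fell (median 1.01; 14 higher and 9 lower on library totals; camera adjusted p = 0.00019; adjusted p = 0.183 with an estimated correlation). Il10, an anti-inflammatory cytokine (gene 16153, mm10 chromosome 1, 131019845 to 131024970), rose from 0.0809 ± 0.0191 to 63.96 ± 20.6 CPM (9.58 ± 0.38; adjusted p = 2.03e-07 by edgeR). The cytokine signalling inhibitors Socs3 (4.73) and Socs1 (4.58) rose. Cd274, which encodes the inhibitory ligand PD-L1 (mm10 chromosome 19, 29362107 to 29388095), rose from 146 ± 13.5 to 1029 ± 152 CPM (2.82 ± 0.14), and the tryptophan-degrading enzyme gene Ido1 from 0.804 ± 0.0241 to 2.67 ± 0.836 CPM (1.73 ± 0.28). Aldh1a2, an enzyme of retinoic acid synthesis, rose from 82.6 ± 4.304 to 144 ± 27.1 CPM (0.80 ± 0.14; adjusted p = 0.00122 by edgeR), and its change was 0.12 with an adjusted p of 0.479 on library totals. The 5 members that fell, named after their values were seen, were the ectonucleotidase genes Nt5e (−2.99) and Entpd1 (−0.32), the inhibitory receptor genes Vsir (−2.31) and Cd200r1 (−1.67), and Tsc22d3 (−0.64), and Entpd1 was not called without PBS replicate 1 (adjusted p = 0.0552).

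Tgfb1 (mm10 chromosome 7, 25687002 to 25705077) differed by less than the spread between replicates, from 42.5 ± 5.47 to 32.8 ± 19.9 CPM (−0.38 ± 0.35; adjusted p = 0.379 by edgeR), and stood at −1.04 with an adjusted p of 0.0363 on library totals. Wikim0185 replicate 1 decided this value, since without it the log2 fold change was −0.97 with an adjusted p of 0.000341. In the Wikim0185 libraries the CPM of Il12b was 217 ± 24.1 times that of Il10. CPM is not corrected for transcript length, so this is a ratio of counts and not of transcript numbers.

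**Figure D3:**
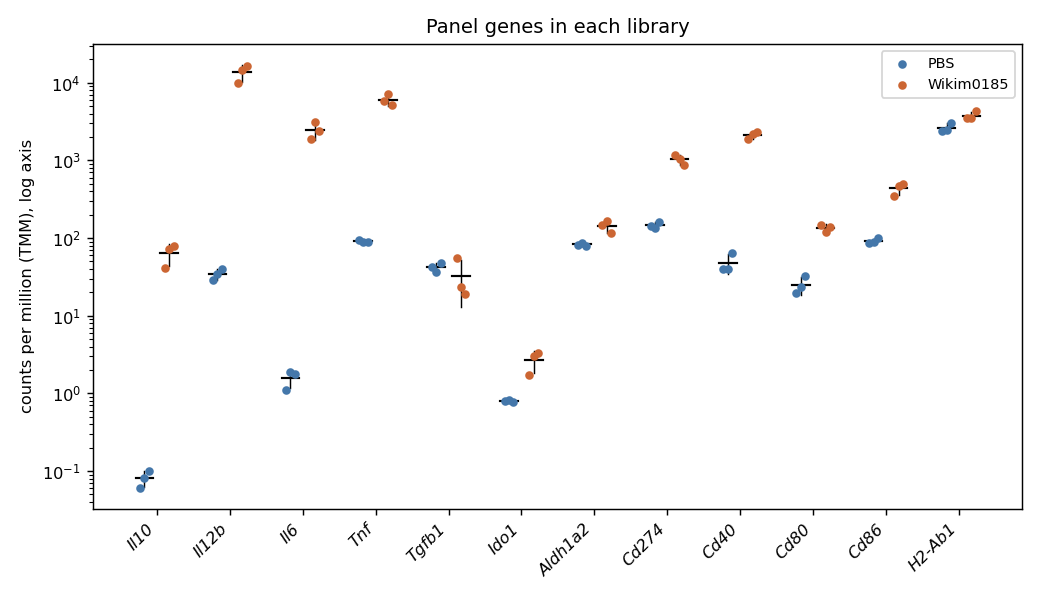
CPM (y axis, log scale, TMM scaling) of the 12 panel genes (x axis) in each PBS (blue) and Wikim0185 (orange) library, with a bar at the mean and a vertical line of 1 SD to each side. Il10, Il12b, Il6, Tnf and Cd40 show wide gaps between the groups, and the Tgfb1 values overlap.

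T-helper 2 and Notch-ligand genes rose in 14 of 19 cases and fell in 2 (median 1.16; camera adjusted p = 0.000605; adjusted p = 0.138 with an estimated correlation). On library totals 9 rose and 5 fell. The Notch ligand genes Dll4 (8.10, on 4 counts in PBS) and Dll1 (3.10) rose, as did Tslp (4.59), a cytokine of type 2 immunity, which went from 0.129 ± 0.0186 to 3.15 ± 0.768 CPM. The 2 that fell, named after their values were seen, were the Notch ligand gene Jag2 (−1.44) and Il1rl1 (−2.36), the receptor of interleukin-33.

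Genes for enzymes of chromatin modification moved in both directions, and camera called none of their 3 lists. Fry called the histone acetylation and histone methylation lists lower (adjusted p = 0.0207 and 0.0465) and did not call the DNA methylation list (0.149). Of the 12 DNA methylation genes, 2 rose and 5 fell (median −0.20; camera adjusted p = 0.628), against 2 and 8 on library totals. The demethylating enzyme gene Tet2 rose from 83.4 ± 13.2 to 190 ± 38.5 CPM (1.19 ± 0.17) and the methyl-DNA-binding gene Mbd2 rose (1.04; adjusted p = 0.0886 by limma-trend on FPKM), while Tet3 fell from 37.7 ± 2.92 to 18.1 ± 7.398 CPM (−1.06 ± 0.24). The other 4 that fell, named after their values were seen, were the maintenance methyltransferase gene Dnmt1 (−0.99), its partner Uhrf1 (−0.95), Dnmt3b (−0.87) and Mbd3 (−0.75), of which Mbd3 was not called without any 1 of the PBS libraries or without Wikim0185 replicate 2 or 3 (adjusted p 0.0681 to 0.136), nor with length and GC trends removed (0.134). Of 29 histone acetylation genes, 6 rose and 12 fell (13 when adjusted over the list alone; median −0.33; camera adjusted p = 0.246), against 2 and 22 on library totals. Falls included the deacetylase genes Hdac5 (−2.29 ± 0.12), Hdac10 (−1.88 ± 0.34) and Sirt3 (−1.78 ± 0.21). Among the 6 that rose was the acetyltransferase gene Kat2b, named after its value was seen. It went from 35.87 ± 1.85 to 118.8 ± 7.98 CPM (1.73 ± 0.1). Of 38 histone methylation genes, 6 rose and 15 fell (median −0.29; camera adjusted p = 0.158). The methyltransferase gene Setdb2 rose from 18.2 ± 2.84 to 131 ± 19.7 CPM (2.85 ± 0.15), the demethylase gene Kdm4a rose from 160 ± 22.2 to 497 ± 27.2 CPM (1.63 ± 0.12), and Setd7 fell (−1.49 ± 0.18). On library totals 32 of the 38 fell and 2 rose.

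Of the NRF2 and oxidative stress genes, 12 of 16 rose and 0 fell (median 1.21; camera adjusted p = 2.44e-05; adjusted p = 0.138 with an estimated correlation). On library totals 10 rose and 4 fell. The peroxiredoxin gene Prdx1 rose from 1539 ± 167 to 6483 ± 971 CPM, the autophagy receptor gene Sqstm1 from 853 ± 40.8 to 3590 ± 116 CPM and the cystine transporter gene Slc7a11 from 758 ± 53.2 to 2952 ± 150 CPM. The other lists of metabolism and stress were not called by camera. Glycolysis genes rose in 13 of 22 cases and fell in 4 (median 0.33; on library totals −0.36, with 6 higher and 12 lower), with a rise of the transporter gene Slc2a6 (2.04) and of Hk3 (1.87) and a fall of Pfkfb4 (−1.39). The other members of the metabolic and stress lists named here for small counts were chosen after their values were seen. The glucose and lactate transporter genes Slc2a3 (−1.04), Slc16a3 (−0.80) and Slc2a1 (−0.45, not called without PBS replicate 1 or 2 or Wikim0185 replicate 2 or 3, adjusted p 0.0675 to 0.0896) also fell. Of 29 oxidative phosphorylation genes, 5 rose and 0 fell (median 0.16; on library totals −0.52, with 1 higher and 24 lower), with the largest change in Uqcrfs1 (1.10). The other 4 were Cox5a (0.51), Atp5b (0.49), Cox6c (0.48) and Cox4i1 (0.44), whose changes were −0.18, −0.20, −0.21 and −0.25 on library totals, that of Cox4i1 with an adjusted p of 0.0247. Camera called this list without Wikim0185 replicate 1 (median 0.19, adjusted p = 0.00798). Cholesterol biosynthesis genes split into 11 higher and 5 lower of 22 (median 0.34; on library totals −0.35, with 2 higher and 11 lower), with Idi1 (1.32) higher and Dhcr7, which makes the last step to cholesterol, lower (−2.76). Mvd (−0.44; adjusted p = 0.192 with length and GC trends removed), Stard4 (−0.52, not called without PBS replicate 1 or Wikim0185 replicate 2 or 3, adjusted p 0.059 to 0.0677) and Nsdhl (−0.30, not called without PBS replicate 1 or 3 or Wikim0185 replicate 2 or 3, adjusted p 0.0507 to 0.121) were also lower. Lysosome genes gave 12 higher and 4 lower of 22 (median 0.35; on library totals −0.34, with 2 higher and 11 lower), with the proton pump gene Atp6v1h (1.38) higher and the lysosomal transcription factor gene Tfeb (−1.36), the glycosidase gene Gusb (−0.71) and the cholesterol transporter gene Npc1 (−0.31, not called without PBS replicate 1, 2 or 3 or Wikim0185 replicate 2 or 3, adjusted p 0.0821 to 0.184) lower. Of 14 genes of endoplasmic reticulum and amino acid stress, 7 rose and 4 fell (median 0.36; on library totals −0.32, with 5 higher and 7 lower), with Ppp1r15a (1.9) higher and Herpud1 (−1.98), Sesn2 (−0.84), Sdf2l1 (−0.35, not called without PBS replicate 1 or 2 or Wikim0185 replicate 1, 2 or 3, adjusted p 0.0567 to 0.102) and Dnajb9 (−0.32, not called without PBS replicate 1 or 2 or Wikim0185 replicate 2, adjusted p 0.0616 to 0.115) lower. With size factors Nsdhl, Npc1, Sdf2l1 and Dnajb9 were not called either (adjusted p 0.0621, 0.0885, 0.055 and 0.0531). The camera adjusted p of these 5 lists was 0.109, 0.16, 0.158, 0.104 and 0.24, and the fry adjusted p 0.00435, 0.218, 0.021, 0.0312 and 0.0061.

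Cell cycle genes fell, with 19 of 25 lower, 2 higher and a median of −1.22 (camera adjusted p = 0.000605; adjusted p = 0.651 with an estimated correlation). On library totals 22 fell and 2 rose. The kinetochore gene Cenpf fell from 23.2 ± 6.998 to 2.36 ± 0.414 CPM (−3.30 ± 0.25), and the mitotic kinase genes Plk1 (−2.28 ± 0.25) and Bub1b (−2.24 ± 0.11) fell with it. The 2 members that rose, named after their values were seen, were Tyms (1.64) and Ccne1 (1.10), which act in thymidylate synthesis and at entry into DNA replication. Alongside, 7 of 12 macrophage markers and 4 of 11 neutrophil markers fell. Of 11 immediate-early genes, 2 rose and 5 fell (6 when adjusted over the list alone; median −0.48; camera adjusted p = 0.246), against 2 and 8 on library totals. Nr4a3 was higher (2.12) and Egr3 (−2.94) and Myc (−2.11) lower. Named after their values were seen, Junb was the other riser (1.2), and Egr2 (−2.04), Egr1 (−1.05) and Fos (−0.96) also fell.

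Markers of conventional dendritic cells moved both ways, with 5 of 12 higher and 2 lower (median 0.04; on library totals −0.65, with 3 higher and 7 lower; camera adjusted p = 0.403). Irf8, a transcription factor of the lineage, rose from 191 ± 33.6 to 857 ± 74.3 CPM, Cd226 rose (1.17; adjusted p = 0.0735 by limma-trend on FPKM) and Clec9a fell (−2.10). Chosen after their values were seen, Xcr1 (2.26, on 27 counts in PBS), Zbtb46 (0.82; 0.13 with an adjusted p of 0.474 on library totals) and Dpp4 (0.48, not called without PBS replicate 1 or 2, adjusted p 0.0763 to 0.0784; −0.21 on library totals) were the other risers, and Batf3 fell (−0.63; adjusted p = 0.0528 with length and GC trends removed). Among 12 macrophage markers 3 rose and 7 fell (8 when adjusted over the list alone; median −0.46; camera adjusted p = 0.295), against 2 and 9 on library totals. The Fc receptor gene Fcgr1 (2.48) and Mertk (2.29) rose, as did Adgre1 (0.46, not called without PBS replicate 1, adjusted p 0.0553; −0.23 on library totals), Cd163 fell (−4.77, on 5 counts in Wikim0185), and Csf1r fell from 1027 ± 40.2 to 264 ± 62.2 CPM. Adgre1 and Csf1r were named after their values were seen. Among 11 neutrophil markers 0 rose and 4 fell (median −0.10; camera adjusted p = 0.37), against 0 and 8 on library totals, with Cxcr2 (−2.50), Mmp8 (−1.29), Retnlg (−1.11, not called without PBS replicate 1 or 2 or Wikim0185 replicate 1 or 3, adjusted p 0.0525 to 0.0802) and, named after its value was seen, Csf3r (−0.98) lower. Mast cell and basophil markers gave 1 higher and 2 lower of 9 (median 0.63; on library totals −0.04, with 1 higher and 2 lower; camera adjusted p = 0.643), the higher being Hdc (3.19), the histamine-forming enzyme, and the lower Gata2 (−1.35) and Kit (−1.17). Eosinophil markers gave 6 higher and 1 lower of 8 (median 0.48; on library totals −0.20, with 0 higher and 2 lower; camera adjusted p = 0.189), with Siglecf lower (−0.99). Il5ra (1.01, not called without PBS replicate 1 or 2, adjusted p 0.063 to 0.0713) and Epx (0.72) were higher, and neither was called on library totals (adjusted p = 0.355 and 0.854).

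Of 5 measured T cell markers 2 rose and 1 fell, with a median of −0.22 and a mean of 0.64 (camera adjusted p = 0.621), and 2 rose and 2 fell on library totals. Lck was higher (4.14), Il7r was higher (0.95; adjusted p = 0.0532 by limma-trend on FPKM) and Cd28 lower (−1.40). Of 5 plasmacytoid dendritic cell markers 2 rose (Bst2 2.54, Tcf4 2.47) and 1 fell (Spib −2.10), with a median of −0.13 and a mean of 0.33 (camera adjusted p = 0.621). On library totals 2 rose and 2 fell. Of 7 stromal markers 2 rose and 0 fell (median 0.43; on library totals −0.25, with 1 higher and 2 lower; camera adjusted p = 0.255). Kdr, a receptor of vascular endothelial growth factor, rose from 3.29 ± 0.814 to 141 ± 10.3 CPM, and Cdh5, named after its value was seen, was the other riser (2.03, not called without PBS replicate 3 or Wikim0185 replicate 1, adjusted p 0.0508 to 0.0584; adjusted p = 0.0727 on library totals). Natural killer cell, B cell and erythroid markers had 2, 2 and 1 measured members and were not tested as lists. Both natural killer cell markers fell, with Klrd1 going from 8.49 ± 2.12 to 0.998 ± 0.1299 CPM and Klrb1c, named after its value was seen, from 52 counts in the 3 PBS libraries to 0 in the 3 Wikim0185 libraries. Neither B cell marker was called, and the erythroid marker was called only when adjusted over the list alone.

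Of the signs of RNA quality, the 13 mitochondrially encoded genes gave 1 rise and 0 falls (COX2 0.44, −0.24 on library totals; list median 0.15 and mean −0.07; on library totals median −0.54, with 0 higher and 10 lower; camera adjusted p = 0.454). The nuclear long non-coding RNAs and snoRNA hosts gave 0 rises and 3 falls of 7, Kcnq1ot1 (−2.14), Snhg1 (−1.25) and Snhg12 (−0.92), with a camera adjusted p of 0.104, which was 0.028 without Wikim0185 replicate 1. On library totals 7 fell and 0 rose. The 7SL and 7SK RNAs, abundant small non-coding RNAs, took 11.76 to 13.04% of the counts in PBS and 9.19 to 11.99% in Wikim0185 libraries. In all, camera called 11 lists higher and 1 lower of 32, with 0 called when the correlation was estimated (8 at an unadjusted p under 0.05); fry called 20 higher and 5 lower. Beyond the lists given above with a fry value, those called by fry and not by camera were the nuclear long non-coding RNAs and snoRNA hosts (fry adjusted p = 0.00023), the immediate-early genes (0.0378) and the markers of T cells (0.00155), plasmacytoid (0.00187) and conventional dendritic cells (0.0184) and stromal cells (0.00188). Other splits of the 6 libraries into 3 and 3 gave up to 15 lists called by camera. Part of the treatment difference stays between the groups of each such split, so that count is no measure of false calls. Counts of members adjusted over the list alone were the same as over all genes in 30 of 35 lists.

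Some named genes share their position with another counted gene, so their counts are uncertain where reads could be given to either. They included Il27 with Apobr, Cd274 with Plgrkt, Setdb2 with Gm45935, Sirt3 with Ric8a, Cd163 with a long non-coding RNA and Cd80 with 2 pseudogenes. Kcnq1ot1 overlaps Kcnq1, and Snhg1, Snhg12 and Atp5b overlap small RNA genes. Long non-coding RNAs overlap Cx3cr1, Gata2, Nlrc5, Tnfsf15, Setd7, Prdx1 and Cd274. Their mean count was 30 against 342 for Cx3cr1 and 20 against 102 for Gata2. Sirt3 had a mean of 156 counts against 3041 for Ric8a, and Cd163 had 38 against 275. Members of the histocompatibility, Cxcl, Iigp and interferon-induced families also have near-identical copies that can exchange reads.

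The deposited FPKM gave a similar ordering of genes with another balance of directions. Limma-trend on log2(FPKM + 1) called 8999 of 11146 genes, 1515 higher and 7484 lower, with a median log2 fold change of −0.59 on that scale, which understates changes of low genes. Of these, 5439 were also called from the counts, and 501 of the shared calls had the opposite direction. Across 11037 genes the fold changes of both sources had a Spearman correlation of 0.98; genes are not independent replicates.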

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

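Protein-coding genes alone and removal of the length and GC trends were chosen after the data had been seen. Over the alternatives, 2823 of 2937 values for 187 named genes kept their direction and side of the threshold, and 442 of 478 list values did; 93 gene values lost the call, 3 gained it and 18 changed sign. Genes called ran from 7992 to 10388 when 1 library was left out (3863 to 4972 higher, 4129 to 5416 lower), lists called from 12 to 15, genes called from FPKM from 8299 to 9212, and the first component's share from 90.6 to 92.4%; that share was 86% on 2000 genes. Library totals gave 2077 higher and 9684 lower, and deposited FPKM 1515 and 7484; both scales follow the library totals. A 2-fold minimum gave 4876 genes (2386 higher, 2490 lower) and glmTreat against 1.5-fold 5106 (2544 higher, 2562 lower), by construction fewer. DESeq2 called 9370 genes, of which 8876 were shared, and limma-voom 9651. Camera with an estimated correlation called 0 lists, and the cause was not tested; fry, which asks another question, called 25. On library totals the sign turned for H2-Eb1 (−0.15), H2-Ab1 (−0.17), Cox5a (−0.18), Atp5b (−0.20), Cox6c (−0.21), Dpp4 (−0.21), Adgre1 (−0.23), COX2 (−0.24) and Cox4i1 (−0.25), and the direction of the test turned for the lists of MHC class II (median −0.40), oxidative phosphorylation (−0.52) and mitochondrially encoded genes (−0.54), and of these only Cox4i1 was called there (adjusted p = 0.0247). The medians of 9 other lists turned there with the direction of the test kept, those of pattern recognition, glycolysis, cholesterol, endoplasmic reticulum stress and lysosome genes and of conventional dendritic cell, mast cell and basophil, eosinophil and stromal markers. On FPKM the 9 genes gave −0.18, −0.20, −0.21, −0.23, −0.24, −0.22, −0.29, −0.27 and −0.28 in the same order. The direction of the T cell markers' test turned with no filter (median −1.47) and a stricter filter (−0.27), and that of mast cell and basophil markers with a stricter filter (−0.25) and without Wikim0185 replicate 3 (−0.09, in a range of −0.09 to 0.77 over the libraries left out); the cause was not tested, and neither list was called in any of these fits. With the replicate block 9007 genes and 13 lists were called; the added list was MHC class II (adjusted p = 0.0397), and Nsdhl (adjusted p = 0.0586), Dnajb9 (0.0543) and Atp6v1g2 (0.0533) were no longer called. Same-numbered libraries correlated in their deviations at 0.053, 0.152 and −0.029. The value of 0.152, for replicate 2 of both groups, was the highest of all pairs. PBS replicate 3 correlated best with Wikim0185 replicate 1 (0.118). These values do not settle whether the numbers mark pairs. They were not taken as pairs because the labels do not say so. Protein-coding genes alone gave 8103 calls, and removal of the length and GC trends 9052, of which 8210 were shared. In the simulation 23% of 1.5-fold changes were found. Far fewer genes were changed there than were called here, so this share need not hold for this comparison. Small changes among genes that were not called stay open.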

Other observations

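Chosen after the results were seen were the gene families, the splits for genes, and the tests on counts taken by risen genes, on other cells' markers, on the length and GC trend, on the median in length classes and on the difference between 2 lists, as was the rule that decided the test of a weaker response. Outside the fixed lists, 14 families defined by symbol were examined, and none was called by camera with an estimated correlation (lowest adjusted p = 0.0918). The Schlafen genes, interferon-induced regulators of translation and growth, rose in 7 of 7 cases (median 4.45), with Slfn5 going from 103 ± 10.6 to 2303 ± 264 CPM and Slfn8 from 35.8 ± 1.28 to 814 ± 74.7 CPM. The guanylate-binding proteins, GTPases of defence within the cell, rose in 9 of 10 cases (median 3.51), with Gbp6 at 5.94 and Gbp4 at 5.62. All 7 STAT transcription factor genes rose (median 1.91), with Stat2 at 3.16. Serpins, inhibitors of proteases, rose in 14 of 20 cases and fell in 2, Serpinb10 (−3.96; adjusted p = 0.0514 by DESeq2) and Serpinb8 (−1.37; median of all 2.12), with Serpinb2 from 16.6 ± 7.77 to 612 ± 246 CPM. The 3 measured formyl peptide receptor genes rose, Fpr1 (2.09), Fpr2 (2.65) and Fpr3 (4.15, on 5 counts in PBS). Of 38 proteasome subunit genes 35 rose and 1, Psmd5 (−0.40, not called without PBS replicate 1 or 2, adjusted p 0.0681 to 0.0734), fell (median 0.69, 0 on library totals), and of 16 subunits of the vacuolar proton pump 13 rose and 2 fell (median 0.76, 0.08 on library totals), Atp6v0a2 (−0.52) and Atp6v1g2 (−1.04, not called without PBS replicate 1, 2 or 3 or Wikim0185 replicate 2 or 3, adjusted p 0.0526 to 0.198; 0.0836 by DESeq2). Psmb6 (1.83) and Psma5 (1.69) of the first and Atp6v1d (1.77) of the second stood above zero on either scale.

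Among families with more lower than higher members, the zinc finger genes named Zfp gave 198 lower and 39 higher of 342 (median −0.54), with Zfp36l2, which promotes decay of AU-rich transcripts, going from 67.3 ± 5.17 to 5.703 ± 1.400 CPM, and Zfp558 higher (3.13). Kinesins fell in 18 of 32 cases and rose in 8 (median −0.92), led by the mitotic motor genes Kif18b (−2.80) and Kif22 (−2.48). Replication-dependent histone genes fell in 6 of 8 cases (median −0.78). Cd300 receptor genes fell in 7 of 11 cases and rose in 0 (median −0.94), with Cd300a from 82.1 ± 6.11 to 11.96 ± 2.600 CPM. C-type lectin genes named Clec fell in 14 of 22 cases and rose in 3 (median −0.88), the risers being Clec4e (3.55), a sensor of mycobacterial glycolipid, Clec4d (2.03) and Clec2d (1.44). Cytosolic ribosomal protein genes rose in 21 of 79 cases (median 0.30), which is −0.40 on library totals. Camera at the preset correlation gave adjusted p = 1.43e-06 for the Schlafen and the Zfp genes, 1.26e-06 for the guanylate-binding proteins, 0.000812 for the proton pump and 0.00969 for the Cd300 receptors; with an estimated correlation the adjusted p was 0.0918 for the first 2 and 0.136 for the other 3. For the proteasome, serpins, STAT genes and formyl peptide receptors it gave 1.56e-07, 2.19e-05, 0.000144 and 0.0149, and the adjusted p was 0.256 for each with an estimated correlation. For kinesins, histones, Clec genes and cytosolic ribosomal proteins it gave 0.0249, 0.0149, 0.0397 and 0.000592, and with an estimated correlation the adjusted p was 0.401, 0.401, 0.379 and 0.634. Mitochondrial ribosomal proteins, with 10 higher and 21 lower of 78, were not called (adjusted p = 0.387). Histones, Schlafen genes and guanylate-binding proteins have near-identical copies that can exchange reads.

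Against library totals the median gene stood at a log2 change of −0.77 in Wikim0185 as computed from group means, with a range of −0.80 to −0.74 when 1 library was left out. Counts taken by the 1110 genes that rose over 4-fold account for part of it at most. The median of all tested genes stayed at −0.45 (−0.48 to −0.43) with these genes left out of the totals. Leaving out the 7SL and 7SK RNAs gave −0.80. A first form, which dropped the 1110 genes from the median too, gave −0.53. It was replaced after its value was seen because it lowers the median by construction. The 3348 genes called higher by less than 4-fold were not left out. They held 46.84 ± 0.22% of the counts in PBS and 49.91 ± 1.08% in Wikim0185 libraries. Whether counts taken by all risen genes together account for the shift was thus not tested. Transcript length as the whole cause is argued against, because the median lay at −0.47 or lower in each of 10 length classes on totals of genes with a known length, where a distortion by length alone would leave some class at 0 or above; a part is left open, since it ran from −0.47 in the shortest to −0.88 in the longest class, and this test replaced one between abundance classes that did not bear on the median. From the lowest to the highest of 4 abundance classes the median log2 change was −0.21, −0.41, −0.15 and 0.35 (−0.89, −1.1, −0.84 and −0.34 on library totals), so only the highest class stood apart and the other 3 did not follow abundance. Abundance was taken over all 6 libraries, so a gene that rose was also lifted in class. The higher median of the highest class is therefore partly built in, and no conclusion is drawn from it. A hypothesis that these tests leave open, and that these classes cannot test, is that expression shifted towards the most abundant transcripts. Classes of abundance independent of the change were not formed, and a change in total RNA per cell was not analysed here.

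The fall of cell cycle genes may reflect fewer dividing cells. The members did not fall by a like amount, since the SD of their log2 fold changes was 7.25 times their median standard error. This spread cannot decide the question, because a member also expressed in cells that do not divide would fall less. Tyms and Ccne1 rose, which argues against a lower share of dividing cells as the only change for these 2 genes. A loss of neutrophil precursors or macrophages cannot be told apart from a lower share of dividing cells, since the markers of these cells lay above the cell cycle genes by 0.85 with a resampled range of −0.17 to 1.33. Whether exposure to the bacterium acts on the cycle within the dendritic cells was not tested by these tests, and the number of dividing cells was not analysed here.

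Wikim0185 replicate 1 stood apart from replicates 2 and 3. A weaker response by 0.2 or more is argued against for the changed genes as a set. Genes that rose over 16-fold differed from the other 2 by a median of −0.02 (−0.09 to 0.04 over resampled genes). Genes that fell over 4-fold differed by 0.08 (0 to 0.16). Of the genes that rose over 16-fold, 52% were lower in replicate 1, and single genes differed more. Il12b took 0.817% of the counts in replicate 1 and 1.12 and 1.26% in replicates 2 and 3. Clic5 went the other way, with 1445 counts against 1283 and 716. The bound of 0.2 was set beforehand. The rule that the intervals must lie within it replaced a rule on the sign alone after the values were seen. The sign rule was left because a difference near 0 can take either sign, and by it the response was not excluded. Depth is argued against, because at 1 thinned depth its highest correlation was 0.988, against 0.9923 between the other 2. A trend with transcript length is a candidate cause of part of the pattern, because replicate 1 followed length with a Spearman correlation of 0.38 across 8258 genes (−0.35 to 0.23 in the other libraries; median −0.17 in the shortest and 0.20 in the longest of 5 length classes), and removal of length and GC trends narrowed its spread to replicates 2 and 3 from 0.314 and 0.355 to 0.257 and 0.301. A first test on the correlation alone had come out for length and was replaced after its value was seen by one on the spread, with a bound of 1.2 also set then, and the spread stayed at 1.54 times (1.49 to 1.60) that between the other 2, which argues against the trend as the whole cause; no biological explanation was tested, because the labels give none that differs between replicates.

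The proinflammatory list (19 of 19 higher) and the tolerogenic list (20 higher and 5 lower of 30) were both called higher by camera, though not with an estimated correlation (adjusted p = 0.138 and 0.183). The hypothesis that their members moved alike was tested on the difference of the medians, which was 4.77. Random splits of their 49 genes gave −2.42 to 2.59 in the middle 95%, and the permutation p was 1e-05, the smallest that 1e+05 resamples can give; the genes of a list are not independent. This says that the median change of the cytokine genes was the larger, and nothing about the proteins. The splits of the 6 libraries into 3 and 3, 10 with the real one, are too few for a share under 0.05. The real split called 9370 genes, the only 1 of the 10 with as many, and the highest other split called 0 by edgeR. For the lists called by camera, 7 of the 10 splits gave as many as the real 12, and the highest other split gave 15. Fry called 25 lists in the real split and 0 in each other split. Each other split mixes the treatments within its groups, so the treatment difference enters its spread and the counts of 0 are no measure of false calls. Part of the treatment difference also stays between its groups, so its camera counts are no measure of false calls either.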
